A study of Mus musculus with 2 samples.

How the data were processed

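H3K9ac ChIP-seq was made from the facial prominence of B6NCrl mouse embryos at 13.5 days, of mixed sex and pooled, as 2 biological replicates. Per the labels, both replicates carry the same donor entry and belong to 1 group. The fixation, sonication and library protocols are linked in the labels but their text was not at hand. Control libraries were not analysed here. Per the submitters' file lists, each replicate's peaks were derived from that replicate's alignments and a control file of its own, the pooled peaks from both alignments and both controls, and the replicated peaks from the per-replicate lists and the pooled list. The aligner, the peak caller, their versions and the read filters are not given in the sources used here, so how duplicate reads or reads with several matches were treated is not known.

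The authors deposited peaks in narrowPeak format on mm10. By that format the deposited fold enrichment is a ratio of signal in the peak over control, the deposited −log10 p-value is not adjusted and the deposited −log10 q-value is adjusted by the caller. The largest p in the replicate lists was 0.0097, a lenient limit, so many weak peaks are present in each list. The fold is relative to each library's own control, and read counts, library sizes and coverage were not available. Depth and its precision are therefore unknown, and intervals given here count genes or peaks, not reads.

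The deposited list of replicated peaks was tested on the files before use. Every row was a pooled peak, but only 33730 of 44603 (75.6%) overlapped a peak in each replicate by at least 50% of the length of either peak. The set analysed here was therefore the pooled peaks with that support in both replicates, 33730 peaks covering 39.9 Mb, of which 33723 lay on the assembled chromosomes. This fallback was written down before the data were examined, as were the lists, motifs, tests, thresholds and most alternatives. The deposited list itself was run as an alternative chosen after seeing the data.

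Gene models were GENCODE M21, on the same assembly as the peaks, and sequence came from GRCm38. A protein-coding gene was called marked when a supported peak overlapped the region 1 kb either side of a TSS of any of its transcripts. Supported peaks with gaps of up to 1 kb were joined into domains, and a gene's width is that of the widest domain touching its promoter, which can lie at an alternative TSS, as at Zfhx3, or be shared with a neighbour. Promoter fold enrichment is the highest peak at the promoter in each replicate, and its SD is over the 2 replicates. Distal peaks lay more than 5 kb from every annotated TSS and were assigned to the nearest protein-coding TSS. The CpG ratio, observed over expected, was taken over 500 bp either side of the gene's outermost annotated TSS and cut at 0.4 and 0.6, while marking counted peaks at any TSS of the gene. Control windows for motifs matched the length of the peak, lay 5 to 10 kb away and overlapped no pooled peak. The alternative controls were the nearest in GC of several candidate windows, which narrowed the GC difference without removing it. These windows could lie farther than 10 kb from the peak, so distance changed together with GC.

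Gene lists were 21 sets with 600 symbols, of which 599 matched the annotation, 1 of them through a synonym, and Ahsp had no match. They cover 565 genes, 33 of them on more than 1 list, so the lists are not independent of each other. Marking was tested with Fisher's exact test against the other protein-coding genes. Odds ratios of the lists carry a small constant added to each count, and within CpG classes to each count of each class. These ratios are therefore finite where all members are marked. Multiples of the expected number within CpG classes have a small constant added to the observed and the expected count, which draws them toward 1. Widths were tested by a permutation test of the median log2 width with 100000 resamples, for lists with at least 5 marked members. Distal peaks per gene were tested by a permutation test with 100000 resamples among genes in the same of 10 bins of territory length. Motifs were tested with an exact McNemar test. All tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. All of these tests are across genes or peaks within 1 group, and none is a test across replicates. Neighbouring genes can share a peak, so genes are not independent observations. Replicate differences at lists are given as percentiles among 10000 random lists matched on mean enrichment in 10 bins, with no p. No paired analysis was possible, because there is 1 group and no pairing between replicates. Random placement of peaks was repeated 100 times within chromosomes.

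The named genes followed a rule fixed beforehand. They were the 10 widest promoter domains, the 10 highest promoters, the 3 widest marked and up to 3 unmarked members of each list in alphabetical order, the 10 strongest distal peaks, the 5 genes with most distal peaks, and the 5 largest replicate differences each way. Genes named for other reasons were chosen after their values were seen, namely neighbours sharing a domain and the genes of the closing observations. Promoters of near-identical gene copies are uncertain, because reads that match several places cannot be placed.

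The code was tested on simulated data before use. Overlap counts differed from those of bedtools 2.31.1 in 0 of 12 cases. In the test of marking over 21938 genes, 100% of simulated lists with few marked members and 2.14% of random lists passed. In the test of width over 14396 genes, 100% of lists with doubled width and 1.43% of random lists passed. In the test of distal peaks over 21921 genes, 100% of lists with added peaks and 1.43% of random lists passed. In the motif test on 3000 windows, 100% of planted motifs passed and 0% of the others. Simulated peaks and controls had the same base composition, so false calls from a GC difference were not covered. Alternatives covered the overlap rule, a −log10 q of at least 2, promoter windows of 500 bp and 2 kb, other gaps, distal limits and controls, background within CpG classes, and each replicate alone. With a replicate left out, every peak of the other was used without the support rule, so weaker peaks entered as well. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on unplaced scaffolds were left out of all gene comparisons.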

Results

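Acetylation of lysine 9 on histone H3 (H3K9ac), a mark of active promoters and of some enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominence of mouse embryos at 13.5 days of development. The facial prominence is the outgrowth of neural crest mesenchyme, covered by epithelium, that forms the upper and lower face. The tissue came from B6NCrl embryos of both sexes, pooled. There were 2 biological replicates in 1 group and no second condition, so no difference between groups could be tested. The labels state no question beyond mapping the mark in this tissue. The comparisons below set the replicates against each other, gene lists against the other protein-coding genes, and distal peaks against flanking sequence.

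The deposited values were peak lists on the mouse assembly mm10. Replicate 1 had 80636 peaks and replicate 2 had 73574, and the list called on both replicates together had 127299. Read counts were not available for this work, so the depth of each library is unknown. Many low fold enrichment values, though not most, lay on fixed steps. In the lower 50% of replicate 1 peaks, 48.3% of the values were whole multiples of 0.217 (within 2e-04), and in replicate 2 37.7% were whole multiples of 0.254. The median peak was 15 steps high in replicate 1 and 13 in replicate 2, so the height of the weak peaks on these steps was coarse in both libraries.

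The replicates ranked promoters alike, with Spearman's rho = 0.913 for fold enrichment across promoters. The 10 promoters with the highest mean fold enrichment over control were those of Actb, Tnrc18, Alx4, Rbm39, Irf2bp2, Actg1, Nedd4, Arid1a, Skida1 and Eef1a1. Actb, which encodes cytoplasmic beta-actin, reached 43.5 ± 2.44 (SD, n = 2), and Alx4, a homeodomain factor of the frontonasal mesenchyme, reached 43.2 ± 5.38. Actg1, the gamma-actin gene, stood at 42.2 ± 3.94, Eef1a1, a translation elongation factor gene, at 39.6 ± 0.985, and Arid1a, which encodes a chromatin remodelling subunit, at 41.4 ± 1.55. Across 33723 peaks found in both replicates, the log2 fold enrichment of the replicates correlated with Spearman's rho = 0.877 and Pearson's r = 0.936. These correlations are across peaks, which are not independent replicates. Of the replicate 1 peaks, 42.8% were shared with replicate 2, against 2.55% after random placement. Of the replicate 2 peaks, 48.9% were shared with replicate 1, against 2.79% after random placement. Sharing rose with peak strength. Of the peaks with a −log10 q of at least 10, 99.6% of 16936 in replicate 1 and 99.8% of 16668 in replicate 2 were shared. Shared peaks had a median fold enrichment of 4.98 in replicate 1 and unshared peaks 2.95. In replicate 2 these medians were 5.08 and 3.05. The shared percentage depended on the overlap asked for and on the peaks used, and ranged from 33.2% to 64.8% in replicate 1 and from 36.4% to 67.4% in replicate 2 over the alternatives.

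**Figure D1:**
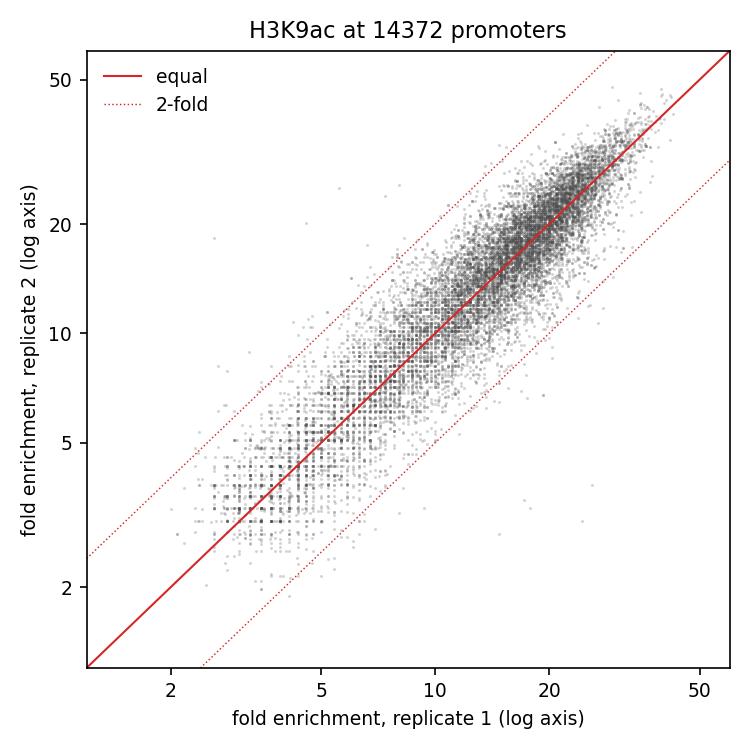
Fold enrichment of the highest H3K9ac peak at each of 14372 promoters in replicate 1 (x axis) and replicate 2 (y axis), both on log axes and with no unit; each point is 1 gene, the solid line marks equal values and the dotted lines a difference of 2-fold. The points follow the line of equal values, and 0.786% of them lie more than 2-fold apart.

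Peaks supported by both replicates gathered at promoters. Of the 33723 supported peaks on assembled chromosomes, 54.1% lay within 1 kb of a transcription start site (TSS) of a protein-coding gene, against 6.13% of randomly placed peaks, whose highest value in 100 placements was 6.58%. Promoter peaks were wider than distal ones, with a median of 1379 bp against 573 bp, and higher, with a median fold enrichment of 11.7 against 3.54. Distal peaks, more than 5 kb from every annotated TSS, made up 23.6% of the set (7946 peaks), against 73.6% after random placement. Of these, 48.1% had their summit in an intron, 45.1% between genes, 4.37% in another exon and 2.44% in an untranslated region. In replicate 1 alone and replicate 2 alone, where unshared peaks are included, the promoter share was 32.8% and 35.3% and the distal share 36.8% and 34.9%. Median widths there were 722 and 704 bp at promoters and 240 and 230 bp at distal peaks, and median fold enrichment 6.07 and 6.61 at promoters and 3.03 and 3.05 at distal peaks.

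The strongest distal peaks stood above the promoter median of 11.7. The strongest lay on chromosome 15 from 85669708 to 85673352 (mm10), in an intron of a gene that is not protein-coding and 61.6 kb from the TSS of Ppara, and had a fold enrichment of 26.0 ± 4.28 (SD, n = 2). Peaks between genes on chromosome 1 lay 37.9 kb from the TSS of Ptma (86486904 to 86488834, 25.4 ± 1.76) and 13.5 kb from that of Tex44 (86439831 to 86444519, 18.9 ± 2.65). Others between genes were 74.2 kb from Chd2 (24.6 ± 0.712), 5.48 kb from Zfp869 (24.8 ± 1.66), 32.4 kb from Pum2 (22.5 ± 2.04) and 41.0 kb from Nufip1 (19.4 ± 2.43). A peak on chromosome 11 from 8622137 to 8625351 lay in an intron of Tns3, 39.2 kb from its TSS, at 20.7 ± 0.809. The remaining strong peaks had their summits in exons of Lca5l (21.9 ± 1.14) and Sorbs3 (18.8 ± 4.12). Distance to the nearest TSS does not say which gene a distal peak acts on.

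Of 21938 protein-coding genes, 14396 (65.6%) had a supported peak within 1 kb of a TSS and are called marked here. The share was 68.4% in replicate 1 alone and 67.8% in replicate 2 alone. Marking followed the CpG content around the gene's outermost annotated TSS, although a marked gene can carry its peak at another TSS. In genes with an observed over expected CpG ratio of 0.6 or more, 9787 of 10078 genes (97.1%) were marked, from housekeeping genes such as Rpl13a and Eef2 to the facial factor Tbx3. Between 0.4 and 0.6, 2539 of 3075 (82.6%) were marked, and below 0.4, 2070 of 8785 (23.6%). The odds ratio between the highest and lowest class was 109 (Fisher's exact test, two-sided, with a p too small for the computer's number format).

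The lists of facial genes were marked throughout or nearly so. All 52 transcription factors of the facial mesenchyme were marked in both replicates (95% confidence interval 93.2% to 100%; adjusted exact p = 3.77e-09), among them Tbx3, Alx1 and Pax3. All 56 genes of facial signalling were marked (93.6% to 100%; adjusted exact p = 1.47e-09), among them Wnt5a, Smad7 and the Hedgehog receptor gene Ptch1. Of 46 genes whose loss causes cleft lip or palate, 44 (95.7%) were marked (adjusted exact p = 8.23e-06). The exceptions were Gad1, which encodes an enzyme of GABA synthesis, and Grhl3, an epithelial transcription factor. Gad1 had a peak in each replicate (4.12 and 3.56) that did not meet the support rule, and Grhl3 had a peak in replicate 1 alone (2.77). Many cleft genes, among them Msx1, Tfap2a, Wnt5a and Ptch1, are also on the mesenchyme or signalling list, so the cleft result is not independent of theirs. Of 30 epithelial genes, 28 (93.3%) were marked (adjusted exact p = 0.00131), with Pitx2 at a fold enrichment of 9.37 ± 0.991, Lama5 at 7.70 ± 2.35 and Esrp1 at 6.94 ± 0.619 (SD, n = 2). Krt15, a basal keratin gene, had a peak in replicate 2 alone (2.58). Of 24 cartilage genes, 21 (87.5%) were marked (adjusted exact p = 0.0439). Trps1 stood at 29.6 ± 8.15, Wwp2 at 17.0 ± 2.56 and Sox6, whose domain also covered the promoter of 1110004F10Rik, at 16.8 ± 0.0823, and the unmarked genes were Col10a1, Matn1 and Snorc, all matrix genes of cartilage. All p values here are from Fisher's exact test against the other protein-coding genes, two-sided and Benjamini-Hochberg adjusted over 21 lists, and they count genes, not replicates. Much of the contrast went with CpG content. Within CpG classes, mesenchyme factors had 1.12 times the expected number of marked genes (adjusted exact p = 0.00133). Signalling genes had 1.17 times (adjusted exact p = 1.36e-05), cleft genes 1.16 times (adjusted exact p = 0.00146) and housekeeping genes 1.12 times. Every mesenchyme, signalling and housekeeping gene was marked, so their multiples are the largest their CpG classes allow and cannot rank these lists. The odds ratios went from 55.2 to 5.87 for mesenchyme factors, from 59.4 to 8.75 for signalling genes and from 9.35 to 3.75 for cleft genes. With every mesenchyme factor and signalling gene marked, their odds ratios are finite only through a constant added to each count. Within classes it is added in each class, so the fall of these ratios is partly set by it. The odds ratio went from 5.98 to 4.31 for epithelial and from 3.22 to 3.02 for cartilage genes (adjusted exact p = 0.000271 and 0.0315). The odds ratio was 14.5 and 43.1 for cleft, 9.36 and 9.11 for epithelial and 7.45 and 4.16 for cartilage genes without replicate 1 and without replicate 2. The marked members behind these ratios hardly differed, in the same order. They were 45 and 46 of 46 cleft genes, 29 and 29 of 30 epithelial genes and 23 and 22 of 24 cartilage genes. With the strongest 50% of the peaks alone, the epithelial and cartilage lists no longer passed (adjusted exact p = 0.942 and 0.358).

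Bone genes were mixed. Of 18 genes, 12 (66.7%) were marked, which did not differ from other genes (adjusted exact p = 1). Satb2 (28.1 ± 0.862, SD, n = 2), Runx2 (23.1 ± 0.123) and Dlx5 (21.4 ± 1.06) had tall promoter peaks, while Bglap, Dmp1 and Ibsp, genes of the mineralised matrix, had none in either replicate. Satb2 and Dlx5 are also on the list of facial mesenchyme factors, so their peaks do not set bone apart from that list. Within the CpG classes cut at 0.4 and 0.6 the bone list was marked more often than other genes, at 1.66 times the expected number (adjusted exact p = 0.0127).

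Genes of other cell types that a dissected face holds were marked less often or no differently. Of 27 skeletal muscle genes, 10 (37.0%) were marked (adjusted exact p = 0.00569). Pax7, a factor of muscle progenitors and neural crest, stood at 9.70 ± 1.71 and Myl4 at 33.3 ± 0.404 (SD, n = 2), although the Myl4 domain also covered the promoter of Cdc27. Acta1 and Actc1, the actin genes of striated muscle, had no peak in either replicate, and the cadherin gene Cdh15 had one in replicate 1 alone (3.12). Of 21 erythroid genes 6 (28.6%) were marked (adjusted exact p = 0.00131), and of 22 macrophage and leukocyte genes 4 (18.2%; adjusted exact p = 1.58e-05). Coro1a (10.4 ± 1.17) and Cd14 (11.5 ± 0.305) were marked, whereas Adgre1, a macrophage surface receptor gene, and the red cell genes Alas2, Epb42 and Ermap had no peak. Of 25 olfactory, eye and pituitary genes, 11 (44.0%) were marked (adjusted exact p = 0.0462). Ebf3 (15.4 ± 0.729), Six3 (7.41 ± 0.672) and Ebf2 (7.28 ± 0.492) were among them, and the lens crystallin genes Cryaa, Cryba1 and Crybb1 were not. Within CpG classes the odds ratio moved from 0.314 to 0.844 for muscle (adjusted exact p = 1), from 0.219 to 0.661 for erythroid and from 0.127 to 0.673 for macrophage genes (0.841 for both), whereas for olfactory, eye and pituitary genes it was 0.415 before and 0.332 within classes, and the call was lost without a smaller effect (0.0803). Leaving out replicate 1 ended the calls of macrophage genes (adjusted exact p = 0.140) and of olfactory, eye and pituitary genes (0.446), and leaving out replicate 2 ended those of muscle (0.339) and of olfactory, eye and pituitary genes (0.130). Leaving out a replicate also dropped the support rule, since all 73558 peaks of replicate 2 or 80627 of replicate 1 were used. Macrophage marking went from 4 of 22 to 11 of 22 in replicate 2 alone and 7 of 22 in replicate 1 alone. The lost calls therefore do not set the library apart from the more lenient peak set. With all pooled peaks the muscle list turned, at an odds ratio of 1.12 (adjusted exact p = 0.834).

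Neuronal, glial and endothelial lists did not pass the test. Of 28 neuronal genes 23 (82.1%) were marked (adjusted exact p = 0.0968), among them Ascl1 (7.91 ± 0.761), Ntrk2 (9.36 ± 0.293) and Prph (4.96 ± 0.901; SD, n = 2). Dcx and Neurod1 had no peak in either replicate. With the strongest 50% of the peaks the neuronal list was marked less often than other genes (adjusted exact p = 0.0147). Of 17 Schwann and glial genes 12 (70.6%) were marked (adjusted exact p = 0.879), with Pmp22 at 18.0 ± 0.384, Metrn, in a domain shared with a neighbouring gene, at 10.8 ± 3.45 and Egr2, a regulator of myelination, at 5.61 ± 0.343. Of 26 endothelial genes 18 (69.2%) were marked (adjusted exact p = 0.879), with Fli1 at 21.7 ± 2.34, Egfl7, in a domain shared with Gm20532, at 11.7 ± 2.82 and Ets1 at 11.3 ± 0.953. Emcn and Flt4 had no peak. Around the Flt4 TSS, 46.6% of the 32-base stretches occur elsewhere in the genome, so its missing peak is uncertain.

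Hox genes, which pattern the body behind the face, were low or unmarked. Of 27 Hox genes of paralogous groups 5 to 13, 6 (22.2%) were marked (adjusted exact p = 1.48e-05). Hoxa7 (6.34 ± 0.0833), Hoxd8 (5.09 ± 1.07) and Hoxd9 (3.82 ± 0.109; SD, n = 2) had the widest domains among them, and Hoxa10 and Hoxa11 had no peak in either replicate. Within CpG classes the list reached 0.262 times its expected number (adjusted exact p = 8.96e-20). Of 12 Hox genes of groups 1 to 4, 5 (41.7%) were marked (adjusted exact p = 0.145). Hoxa1 (4.39 ± 0.391), Hoxd1 (4.00 ± 0.0998) and Hoxd3 (3.71 ± 0.573, in a domain shared with Hoxd4) were marked, and Hoxa2, Hoxa3 and Hoxb1, genes of the hindbrain and the arches behind the jaw, had no peak. Within CpG classes this list too fell below its expected number, at 0.570 times (adjusted exact p = 0.00133).

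Lists of tissues outside the face served as negative references. Of 30 liver genes 4 (13.3%) were marked (adjusted exact p = 3.3e-08), and Alb, Afp and Ahsg, abundant hepatocyte genes, had no peak. The domains of the marked Apoh and Foxa3 also covered the promoters of Prkca and Sympk. Of 26 gut, pancreas and kidney genes 8 (30.8%) were marked (adjusted exact p = 0.00117), and Aqp2 and Cdh17 had no peak. The Sftpc domain (21.2 ± 4.17, SD, n = 2) covered the promoter of its neighbour Bmp1. Of 25 germline genes 4 (16.0%) were marked (adjusted exact p = 2.44e-06). Gdf9 (18.1 ± 3.19) shared its domain with Uqcrq, a mitochondrial complex III gene, and Ddx4, Bmp15 and Acrv1 had no peak. Of 25 heart genes 12 (48.0%) were marked (adjusted exact p = 0.110), with Myl3 at 22.0 ± 1.34 in a domain shared with Pth1r, and Gata6 at 6.16 ± 1.36. Hand1, marked too, is on the heart list and on that of facial mesenchyme factors. All 32 housekeeping genes (adjusted exact p = 7.95e-06) and all 30 cell cycle genes (adjusted exact p = 1.54e-05) were marked. Within CpG classes the liver and cell cycle calls ended (odds ratios 0.309 and 2.05, adjusted exact p = 0.123 and 0.549). Leaving out replicate 2, and with it the support rule, ended the call of the gut, pancreas and kidney list (adjusted exact p = 0.181).

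**Figure D2:**
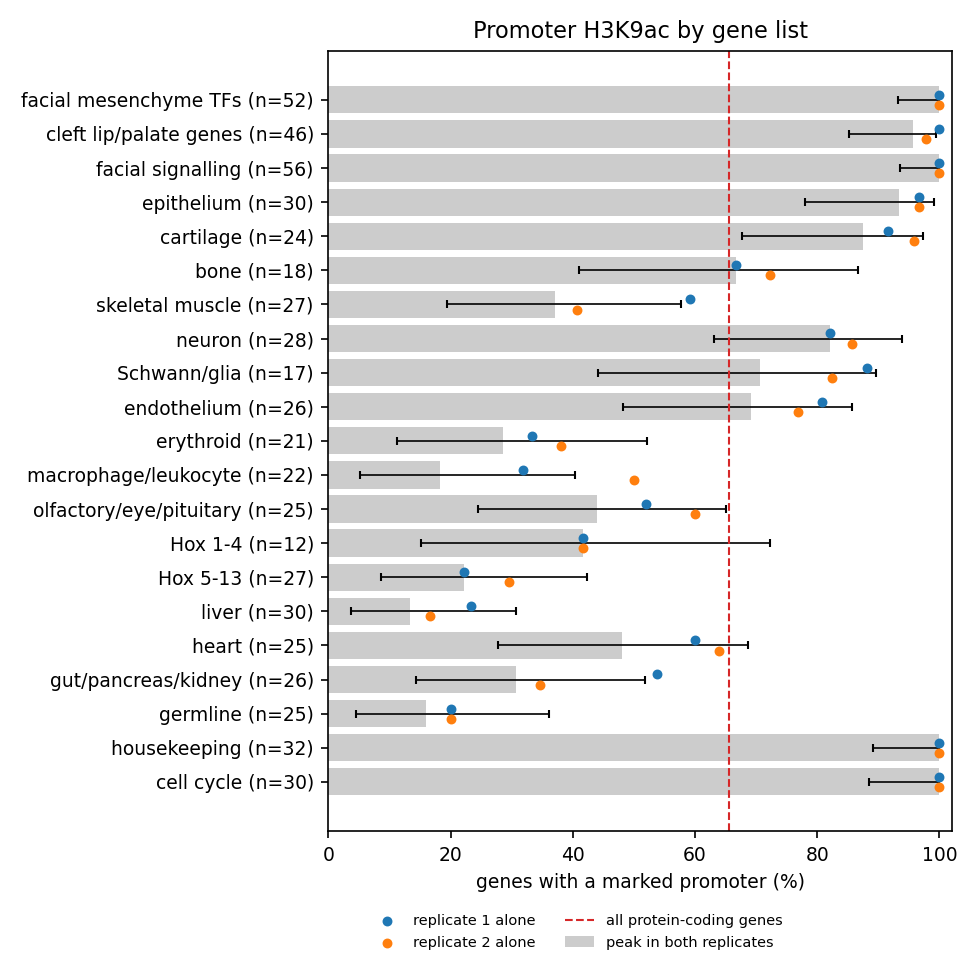
Share of each gene list with an H3K9ac peak at the promoter, in percent (x axis), with the number of genes in each list on the y axis; bars are genes with a peak supported by both replicates, whiskers the 95% confidence interval (exact Clopper-Pearson), coloured points each replicate alone, and the dashed line the 65.6% of all protein-coding genes. Facial mesenchyme factors, signalling genes, housekeeping genes and cell cycle genes stand at 100%, and liver genes at 13.3%.

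Peaks less than 1 kb apart were joined into domains. Tbx3, a T-box factor, had the widest at its promoter, 27.0 kb on chromosome 5 from 119660881 to 119687866, followed by Trps1, a zinc finger repressor, with 23.8 kb on chromosome 15 from 50867951 to 50891794. Pou3f3 (22.0 kb), Bahcc1 (20.4 kb), Bcl9l (20.1 kb), Zfhx3 (20.0 kb), Alx1 (19.3 kb), Pax3 (18.6 kb), Ebf3 (17.1 kb) and Tbx2 (16.7 kb) came next. Fold enrichment was 15.4 ± 0.729 at Ebf3 and 34.5 ± 0.0951 at Tbx2 (SD, n = 2), which had domains of similar width. The median over all marked genes was 2037 bp. Of the 101 genes with a domain over 10 kb, 22 were on the list of facial mesenchyme factors.

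**Figure D3:**
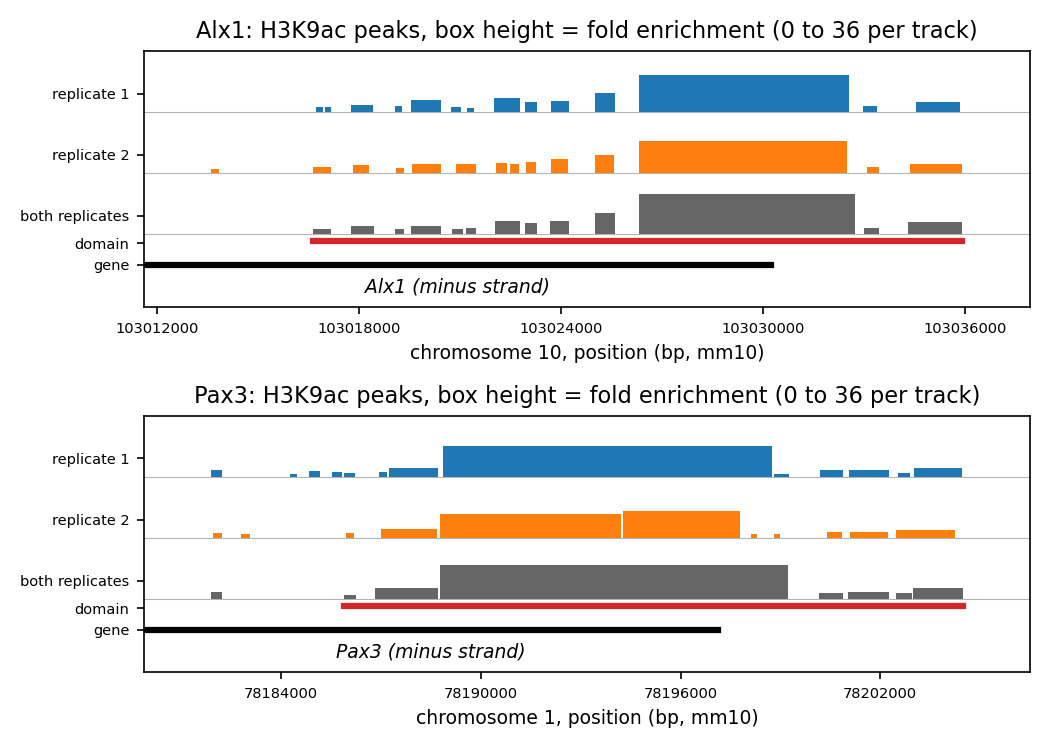
H3K9ac peaks around Alx1 (chromosome 10) and Pax3 (chromosome 1), with the position in bp on mm10 on the x axis; boxes are peaks of each replicate and of the set supported by both, box height is fold enrichment, the red bar is the joined domain and the black bar the gene, both genes lying on the minus strand. The Alx1 domain runs from 103016612 to 103035916 and the Pax3 domain from 78185894 to 78204492, and each covers the start of its gene.

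Domains were wider in several lists, facial and other. Facial mesenchyme factors had a median width of 8240 bp against 2033 bp for other marked genes, a log2 ratio of 2.02, and 49 of 52 were wider than that median (permutation test, two-sided, adjusted p = 0.00012). Signalling genes had a median of 4819 bp (log2 ratio 1.24, 47 of 56 wider) and cleft genes 3572 bp (0.81, 34 of 44 wider), both with an adjusted p = 0.00012 by the same permutation test. The p before adjustment, 2e-05, is the smallest that 100000 resamples can give. Wnt5a (16.6 kb), Tfap2a (16.6 kb) and Mn1 (16.4 kb) were the widest cleft genes, and Smad7 (14.6 kb) and Ptch1 (12.6 kb) followed Wnt5a among signalling genes. Tfap2a and Mn1 are also on the mesenchyme list and Wnt5a on the signalling list, so the cleft width is not an independent result. Bone genes (3550 bp, log2 ratio 0.80, adjusted permutation p = 0.00527) and cartilage genes (3228 bp, 0.66, adjusted permutation p = 0.00292) were wider too, as were housekeeping genes (3276 bp, 0.69, adjusted permutation p = 0.00054) and cell cycle genes (3031 bp, 0.57, adjusted permutation p = 0.00189). Satb2 (16.2 kb), Dlx5 (9.05 kb) and Runx2 (8.03 kb) led the bone list, Rpl13a (9.09 kb, shared with Rps11) the housekeeping list and Ccnd2 (7.72 kb) the cell cycle list. Satb2 and Dlx5 are facial mesenchyme factors too, so the bone width is not separate from that list.

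Domains were narrower at marked genes of several other lists. The median was 647 bp for the 6 marked Hox genes of groups 5 to 13 (log2 ratio −1.65, permutation test, adjusted p = 0.00054) and 653 bp for the 5 of groups 1 to 4 (−1.64, adjusted permutation p = 0.00292). It was 717 bp for gut, pancreas and kidney genes (−1.51, permutation test, n = 8, adjusted p = 0.00054), 925 bp for muscle (−1.14, n = 10, adjusted permutation p = 0.00189), 1261 bp for heart (−0.69, n = 12, adjusted permutation p = 0.0266) and 1446 bp for neuronal genes (−0.49, n = 23, adjusted permutation p = 0.0266). The widest Hox domain was that of Hoxd1, 1.18 kb. For groups 5 to 13 the log2 ratio reached a lower value with 1 replicate left out. Epithelial, glial, endothelial, erythroid and olfactory, eye and pituitary genes did not differ (adjusted p from 0.153 to 0.795, permutation tests). The muscle call ended when covered bases within 5 kb of the TSS were used (adjusted permutation p = 0.197), the neuronal call ended with joins over gaps of 3 kb (0.0623) or without replicate 2 (0.0709), and the gut, pancreas and kidney call without replicate 1 (0.108). The olfactory, eye and pituitary list passed as narrower without replicate 1 (−1.47, adjusted permutation p = 0.00035), and Schwann and glial genes passed as wider with gaps of 3 kb (0.88, 0.0212).

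**Figure D4:**
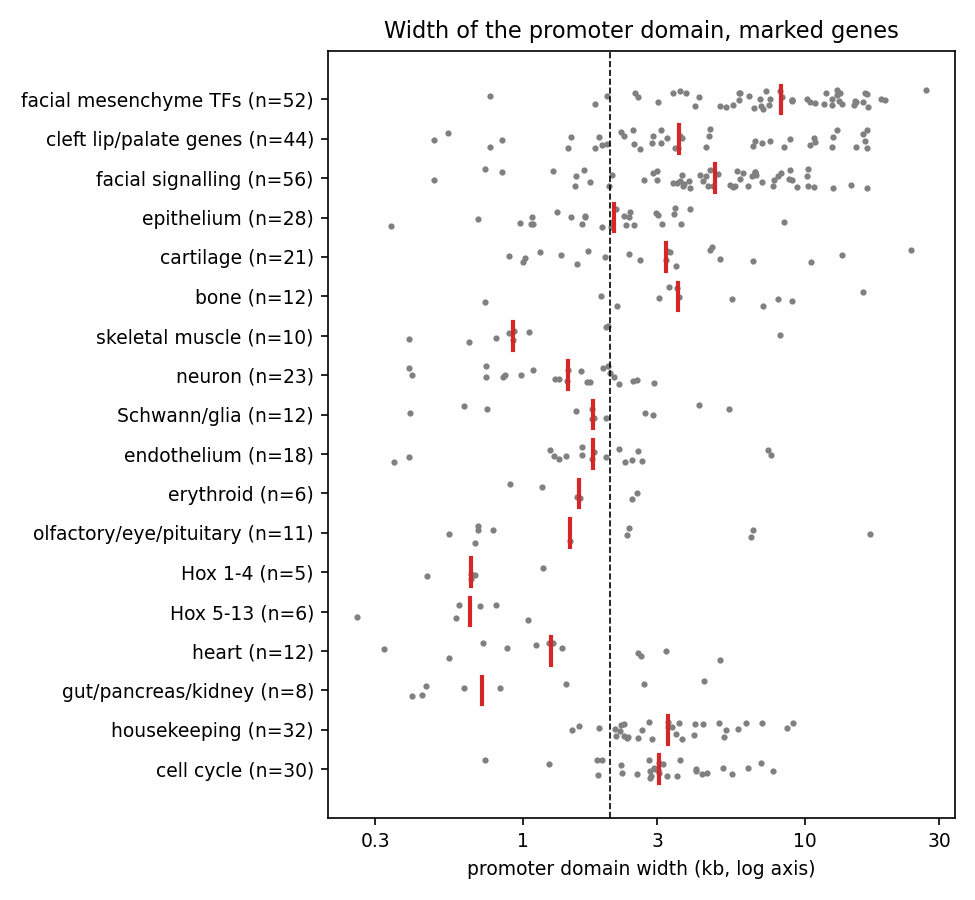
Width of the promoter domain in kb (x axis, log axis) for the marked genes of each list with 5 or more of them; grey points are genes, red bars list medians, and the dashed line the median over all marked genes. Facial mesenchyme factors have a median of 8240 bp and the 2 Hox lists medians of 647 bp and 653 bp.

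Distal peaks gathered near facial mesenchyme factors and signalling genes. With each distal peak assigned to the nearest protein-coding TSS, mesenchyme factors had 2.71 distal peaks per gene against 0.670 ± 0.243 (SD of random draws) in genes with territories of like length, and 39 of 52 had at least 1 (permutation test, two-sided, adjusted p = 0.00042). Signalling genes had 2.48 per gene against 0.689 ± 0.237, and 39 of 56 had at least 1 (adjusted p = 0.00042, permutation test). The excess over matched genes was 2.04 for mesenchyme factors and 1.79 for signalling genes. Its size depended on the peak set, and it was larger with 1 replicate left out and all peaks of the other used. Alx4 had 10, Pax3 9, Tbx3 8, Ptch1 7 and Mn1 13. The most distal peaks lay near Gse1 (57), Zfhx3 (23), Ncor2 (22), a nuclear receptor corepressor gene, Smad7 (20), an inhibitor of BMP and TGF-beta signalling, and Zmiz1 (19). The other 19 lists did not pass. Cleft genes had 1.54 against 0.672 (adjusted permutation p = 0.114) and cartilage genes 1.29 against 0.477 (adjusted permutation p = 0.155), with Trps1 at 9. Hox genes of groups 5 to 13 had 0 distal peaks over 27 genes, against 0.0754 per gene in matched draws (permutation test, adjusted p = 0.676). Without matching on territory, the cleft list, the cartilage list and the Hox list of groups 5 to 13 passed (adjusted permutation p = 0.0172, 0.0458 and 0.0458).

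Sequence motifs in distal peaks were compared with a window of the same length 5 to 10 kb away that held no peak, in 7898 pairs. The palindrome of AP-2 factors such as Tfap2a occurred in 30.1% of peaks and 14.9% of control windows. Pairs with it in the peak alone outnumbered pairs with it in the control alone by 2.66 times (95% confidence interval 2.44 to 2.90, adjusted exact p = 2.79e-123). The CTCF core was in 1.85% against 0.671% (ratio 2.86, 2.06 to 4.03, adjusted exact p = 3.54e-11) and the CAGCTG E-box, a site of myogenic and other bHLH factors listed beforehand as a control motif, in 44.3% against 29.1% (ratio 2.05, 1.91 to 2.21, adjusted exact p = 4.1e-93). With either replicate left out and all peaks of the other used, the CTCF ratio fell below this interval. The nuclear receptor site AGGTCA (ratio 0.798, adjusted exact p = 2.47e-10) and the GATA site, also a control motif (9.51% against 13.3%, ratio 0.681, adjusted exact p = 1.45e-13) were less frequent in peaks. The tests were exact McNemar tests, two-sided and adjusted over 15 motifs. Peaks had a mean GC content of 53.6% and controls 46.6%, and several ratios moved when controls were matched on GC.

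The matching was partial, since the matched controls had a mean GC content of 51.3%, and a GC difference remained in every ratio given with it. The matched windows could also lie farther from the peak than the first controls. Changes between the 2 sets of controls therefore cannot be laid to GC alone. The homeodomain core TAATTA, bound by Alx, Msx, Dlx and Prrx factors, was in 9.50% of peaks and 13.6% of controls (ratio 0.656, adjusted exact p = 8.88e-16). Against GC-matched controls it was more frequent in peaks, 9.51% against 7.24% (ratio 1.37, adjusted exact p = 3.89e-07). Among motifs listed beforehand as controls, CAGCTG (1.44) and MEF2 (2.08) had larger ratios against these windows, while GATA (0.839) and HNF4 (0.975) did not. A ratio of this size is therefore not by itself evidence of facial factors. The forkhead core (ratio 0.470, adjusted exact p = 2.57e-95) and the Sox core (0.833, adjusted exact p = 1.3e-07) were less frequent in peaks against the first controls and did not differ against GC-matched ones (0.960 and 1.03, adjusted exact p = 0.420 for both). The CAGATG E-box bound by Twist1 (ratio 1.09, adjusted exact p = 0.0139) and the TEAD site (1.12, adjusted exact p = 0.00224) lost their calls with GC matching (adjusted exact p = 0.637 and 0.560). Against GC-matched controls the AP-2 and CAGCTG ratios were 1.72 and 1.44 and the CTCF ratio was 2.90, and all still passed against these partly matched controls (adjusted exact p = 4.08e-42, 7.06e-26 and 2.39e-11). The AP-1 site was less frequent in peaks (ratio 0.876, adjusted exact p = 0.0185), a call that ended without replicate 2 (ratio 0.941, adjusted exact p = 0.141) and turned without replicate 1 (1.03, 0.610). An E-box and a homeodomain core within 20 bp of each other occurred in 1.05% of peaks and 1.06% of controls (adjusted exact p = 1; 0.0887 with GC matching). Of the other control motifs, the liver motifs HNF4 (1.00% against 0.962%) and HNF1 (1 peak against 0 controls) did not differ (adjusted exact p = 1 for both), nor did the muscle motif MEF2 (0.988% against 0.861%, adjusted exact p = 0.567), although MEF2 passed with GC matching (ratio 2.08, adjusted exact p = 0.000395).

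**Figure D5:**
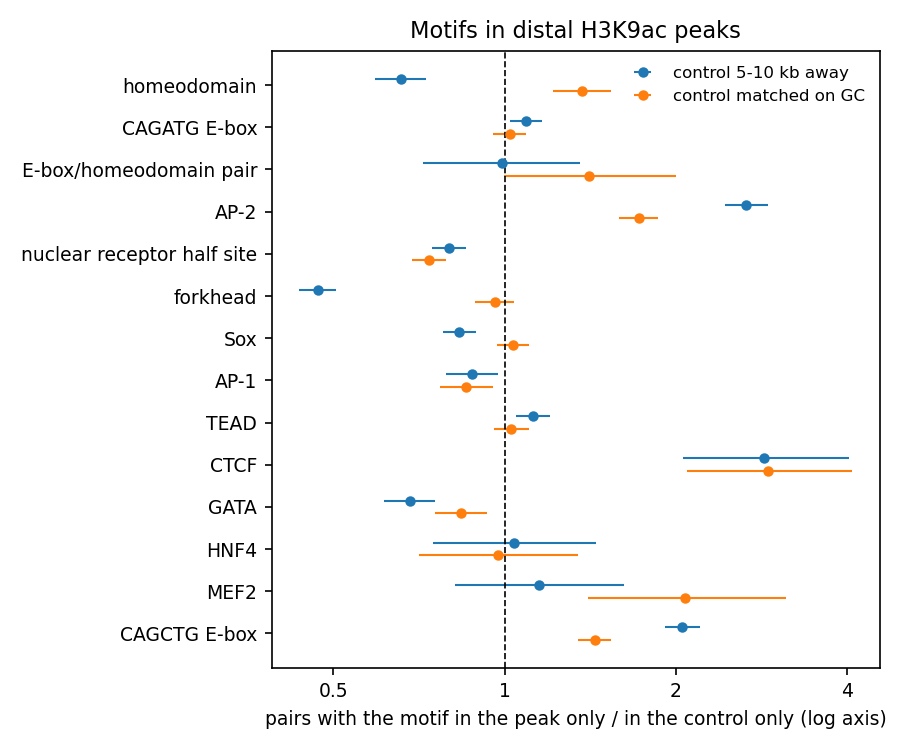
Ratio of pairs with a motif in the distal peak alone to pairs with it in the control window alone (x axis, log axis) for 14 motifs, with 95% confidence intervals; blue points use control windows 5 to 10 kb away and orange points windows chosen to be closer in GC (51.3% against 53.6% in peaks), and the dashed line marks a ratio of 1. The orange windows could also lie farther than 10 kb from the peak. AP-2 stands at 2.66 and 1.72, and the homeodomain core at 0.656 and 1.37.

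Differences between the replicates were small at most promoters. Over 14372 promoters with a peak in each replicate, the log2 ratio of replicate 1 over replicate 2 had a median of −0.043 and an SD of 0.33, and 113 promoters (0.786%) differed more than 2-fold. Epithelial genes stood lowest against random lists of like enrichment, with a median of −0.17 and at the 3.69 percentile of 10000 lists, 9 of 28 lying above the median of all genes. Hox genes of groups 5 to 13 stood at the 5.43 percentile, bone genes at 85.0 and facial mesenchyme factors at 38.9. The bone median lay 0.997 SDs of random lists from the median of all genes, but 2.19 with −log10 p in place of fold enrichment. These SD values are not distances from the random lists themselves. With 18 lists, chance alone places 1 or 2 among the lowest or highest 5%. The largest differences were at Gm49027 (2.60 and 18.3), Gm17349 (5.58 and 25.2), Mvp (4.55 and 20.1), Gmfg (7.37 and 23.9) and Ehbp1l1 (8.02 and 25.6), all higher in replicate 2. Rnf151 (24.5 and 3.05), Gpsm3 (26.0 and 3.82), Ccdc8 (17.8 and 3.31), Ushbp1 (14.7 and 2.80) and Pinlyp (17.2 and 3.49) were higher in replicate 1. At each of these 10 promoters the taller peak overlapped a peak of the other replicate that was of like height, within 0.5 on the log2 scale, but ended outside the promoter window.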

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

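The tests of library scaling and of partial overlap were chosen after the result was seen, and the others before. The deposited list of replicated peaks held 10873 peaks (24.4%) that were not in the analysed set, a signal in data the main comparisons did not use, although the alternatives with this list and with all pooled peaks did. Of these, 5999 overlapped a replicate 1 peak by the 50% rule but no replicate 2 peak, 3986 the reverse, and 888 neither. Their median fold enrichment was 2.88 against 5.11 for the supported peaks. Partial overlap is argued against, since 1.61% touched a peak of each replicate by 1 bp or more. Random placement of the whole set is argued against as well, since 16.4% lay within 1 kb of a protein-coding TSS against at most 5.63% in 100 random placements. The test cannot say how many single peaks among them are random calls. Within 2 kb of a supported peak lay 37.8% of them, against a mean of 6.87% in random placements. All 33730 pooled peaks that met the 50% rule in both replicates were on the deposited list, so the 10873 peaks came in besides them. What else the authors' rule for calling a peak replicated let in stays open, because the rule is not recorded in the sources used here. No biological explanation was tested.

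Of all deposited replicated peaks, 8 lay on scaffolds not placed on a chromosome, and no gene comparison used them.

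The 10 promoters with the largest difference between replicates had a median absolute log2 ratio of 2.35. Scaling of the libraries is argued against, because the median log2 ratio over all promoters was −0.043. Peak boundary placement is consistent with the test written for it, since the median absolute log2 ratio fell to 0.15 when the highest peak within 5 kb of a TSS was taken, and all 10 were then under 0.5. In all 10 the higher replicate's peak overlapped a peak of the other replicate within 0.5 on the log2 scale, for example 24.5 and 24.9 at Rnf151. A candidate explanation for these promoters is therefore the edge of a neighbouring peak, and no biological explanation was tested.

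Of 10078 promoters with a high CpG ratio, 291 had no supported peak, 14 of them Hox genes of groups 5 to 13. Repeated sequence is argued against for the Hox promoters, where the median share of 32-mers found elsewhere in the genome was 0% and the highest 10.3%. The authors' peak threshold stays open there, since 4 of the 14 (28.6%) had a pooled peak, between the bounds set beforehand, and 10 had none. Among the other 277, 89 (32.1%) had 50% or more of their 32-mers elsewhere, against 0.3% of 1000 marked promoters, and 144 had under 5%, so repeated sequence may account for some of them but not for those 144. Of the 277, 90 had a pooled peak, so the authors' peak threshold stays open for them as well. A biological absence of the mark remains untested for all of these promoters.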

How the results depend on the processing

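Alternatives with the deposited replicated list, with basic protein-coding transcripts and with each domain counted once were chosen after seeing the data. HNF1 gave no ratio and is left out. Unknown depth and weak peaks limit lists with few marked genes. For marking, 179 of 210 values kept their direction and side of the threshold, for width 131 of 143, for distal peaks 134 of 147 and for motifs 66 of 84. All 4 alternatives of the CpG result and 51 of 54 of the replicate differences stayed the same. The marking, width and distal calls of facial mesenchyme factors and signalling genes held in every alternative run, though not at the same size. The cause of each change below was not tested.

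Sharing of replicate 1 and replicate 2 peaks was 47.6% and 54.2% with 1 bp of overlap, 33.2% and 36.4% with 50% of both peaks, 51.3% and 53.8% at a −log10 q of at least 2, and 64.8% and 67.4% for equal numbers of strongest peaks. The correlation was 0.877 at that q, 0.893 with −log10 p and 0.856 with the mean of overlapping peaks. The number of peaks ranged from 73558 to 80627 with 1 replicate left out. The share of peaks at promoters was 50.7% within 500 bp, 60.1% within 2 kb, 24.1% for pooled peaks, 44.9% for the deposited list, and 32.8% to 35.3% with 1 replicate left out. The share of genes marked was 65.1%, 66.5%, 70.9% and 66.8% in the same order, and 67.8% to 68.4% with 1 replicate left out.

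Odds ratios of marking with the strongest 50% of the peaks were 1.13 for epithelium and 1.55 for cartilage, which lost their calls, 0.377 for neuron, 0.931 for Schwann and glia and 0.573 for endothelium, which reversed, and 0.0266 for Hox 1 to 4 and 0.322 for heart, which gained calls. Within CpG classes they were 2.83 for bone and 0.118 for Hox 1 to 4, which gained calls, and 0.844 for muscle, 0.661 for erythroid, 0.673 for macrophage, 0.332 for olfactory, eye and pituitary, 0.309 for liver and 2.05 for cell cycle, which lost them. With pooled peaks they reversed for muscle (1.12) and heart (1.53), and calls were lost for macrophage (0.410), olfactory, eye and pituitary (0.713) and gut, pancreas and kidney (0.645). Bone reversed within 500 bp (0.823), within 2 kb (0.969) and with the deposited list (0.955). Heart gained a call within 500 bp (0.425), as did Hox 1 to 4 with basic transcripts (0.293). With 1 replicate left out, odds ratios ranged from 14.5 to 43.1 for cleft genes, 9.11 to 9.36 for epithelium, 4.16 to 7.45 for cartilage, 0.102 to 0.147 for liver, 0.889 to 1.17 for bone, 0.331 to 0.663 for muscle, 0.223 to 0.475 for macrophage, 0.499 to 0.701 for olfactory, eye and pituitary and 0.257 to 0.536 for gut, pancreas and kidney.

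Log2 width ratios of epithelium reversed to −0.16 with gaps of 500 bp and −0.051 for bases covered within 5 kb. With the latter, muscle lost its call (−0.43) and Schwann and glia reversed (0.14). With gaps of 3 kb, neuron lost its call (−0.45), and Schwann and glia (0.88) and olfactory, eye and pituitary (0.29) reversed. With 1 replicate left out they reached 1.34 for bone, −2.63 for Hox 5 to 13 and −1.23 for heart, and ranged from −0.087 to −0.018 for epithelium, −0.60 to −0.49 for neuron, −1.47 to −0.55 for olfactory, eye and pituitary and −2.17 to −0.72 for gut, pancreas and kidney.

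Distal peaks per gene, list minus matched genes, gained a call without matching for cleft genes (1.18), cartilage (0.931) and Hox 5 to 13 (−0.362). They reversed without matching for Hox 1 to 4 (−0.194) and housekeeping (−0.0499), at a 10 kb limit for neuron (−0.0314) and gut, pancreas and kidney (0.0419), and at a 2 kb limit for Hox 1 to 4 (−0.0385). With 1 replicate left out they ranged from 4.22 to 4.80 for facial mesenchyme factors, 3.95 to 4.72 for signalling, −0.248 to 0.193 for neuron, −0.0311 to 0.380 for macrophage, −0.0769 to −0.0633 for Hox 1 to 4 and −0.0306 to 0.154 for housekeeping.

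Motif ratios with partly GC-matched controls reversed for homeodomain (1.37), the E-box and homeodomain pair (1.41), Sox (1.03) and HNF4 (0.975), lost a call for CAGATG (1.02), forkhead (0.960) and TEAD (1.03), and gained one for MEF2 (2.08). With peaks extended by 200 bp, CAGATG lost its call (1.06) and the pair (1.06) and HNF4 (0.847) reversed. MEF2 gained a call with the deposited list (1.38). With 1 replicate left out, the CTCF ratio was 1.79 either way, and ratios ranged from 0.916 to 1.06 for the pair, 0.941 to 1.03 for AP-1, 0.858 to 0.912 for HNF4 and 0.978 to 1.24 for MEF2. The replicate difference from the median of all genes, in SDs of random lists, moved to 2.19 for bone and −0.397 for endothelium with −log10 p, and to −0.423 for housekeeping with ranks.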

Other observations

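The values in this part were chosen after the data were seen, except the bounds of the X chromosome test, which were set before it was run. Gene families differed in marking, and no test was made between them. Of 1135 olfactory receptor genes 2 were marked (0.176%), of 331 vomeronasal receptor genes 1 (0.302%), and of 57 keratin-associated protein genes and 35 bitter taste receptor genes 0. Of all these genes 1, a vomeronasal receptor gene, had a high CpG ratio, and it was marked. Many of these genes have close copies, so their promoters are uncertain. Marked were 78 of 78 mitochondrial ribosomal protein genes, 45 of 46 complex I subunit genes and 93 of 101 cytosolic ribosomal protein genes, of which 69, 39 and 80 had a high CpG ratio. All 6 Dlx genes, which pattern the jaw, were marked, as were 17 of 19 Sox genes, 17 of 19 Wnt genes and 35 of 44 Fox genes. Among those with a high CpG ratio, 6 of 6 Dlx, 14 of 16 Sox, 13 of 13 Wnt and 28 of 31 Fox genes were marked. The share over all genes of that class was 97.1%. Clustered protocadherin genes, used by neurons, were marked in 7 of 57 cases, although 22 of them had a high CpG ratio, 3 of these being marked.

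Several genes with a low CpG ratio at the outermost TSS had broad domains. Kdm6b, a histone demethylase gene, had a domain of 14427 bp, Nfib 14401 bp, the growth factor receptor gene Pdgfra 10748 bp, the retinoic acid hydroxylase gene Cyp26b1 10593 bp and the retinoic acid receptor gene Rara 10224 bp. Tbx15 (9430 bp), Nr2f2 (8193 bp) and Tcf4 (8047 bp) followed among transcription factor genes. Their CpG ratios ran from 0.172 at Kdm6b to 0.398 at Pdgfra. Some of these domains lie at another start site of the gene than the outermost, so they are not evidence about promoters poor in CpG.

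The X chromosome had fewer marked promoters than the autosomes, 448 of 948 genes (47.3%) against 67.0% of 20807, an odds ratio of 0.441 (Fisher's exact test, two-sided, p = 3.1e-34). Single autosomes ran from 54.0% on chromosome 14 and 55.8% on chromosome 7 to 79.0% on chromosome 12, and the p treats genes as independent, so it does not set the X apart from that spread. The hypothesis tested was that X-linked promoters may be marked less often because they hold less CpG. Within the CpG classes the odds ratio was 0.489 (exact conditional test, two-sided, p = 1.59e-15), so CpG content is argued against as the whole account. On the X, 15.7% of promoters of low, 68.8% of middle and 90.9% of high CpG ratio were marked, against 24.5%, 84.0% and 97.3% on the autosomes. The embryos were of mixed sex, so reads per X-linked locus would be fewer than per autosomal locus, and this stays open, as do multicopy X-linked genes. Neither was tested.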
